A study of Mus musculus with 9 samples.

How the data were processed

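Messenger RNA was sequenced from peritoneal exudate cells of Apoe-deficient mice, which the labels call peritoneal macrophages. Per the labels' protocols, 9 samples fell into 2 groups, 5 control samples from mice given citrate buffer and 4 diabetic samples from mice given streptozotocin, a toxin of pancreatic beta cells, at 40 mg/kg on 5 days in a row from 8 weeks of age. Both groups then ate a western diet for 8 weeks. Thioglycollate, an irritant that draws leukocytes into the peritoneal cavity, was injected (1.5 mL at 3%), and 3 days later the cavity was rinsed with 10 mL of phosphate-buffered saline, the cells were spun down and their RNA was extracted. The labels describe no sorting or adherence step. Libraries were made with a SMARTER kit for messenger RNA, per the labels' protocols, and the aligner, the counting tool and the strand setting are not given in the sources used here. The labels do not say whether each sample came from 1 mouse or a pool, so the p-values measure the spread between these samples.

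The authors deposited 1 table of FPKM values (fragments per kilobase of gene and per 1e6 reads) for 41096 genes in the 9 samples, with the gene length, position, strand and biotype of each gene, per the file headers. All 9 sample columns were matched to samples by their titles and 0 columns of sample values stayed unmatched. Every value multiplied by the deposited gene length is a whole multiple of what 1 read is worth in that sample. All values came out whole (100% within 0.05 of a whole number), which gives 14156421 to 16169060 reads in genes per sample. The divisors that the values imply are not the plain totals. They equal median-of-ratios size factors times the geometric mean of the totals, within 6.74e-09 percent, so the deposited FPKM are already scaled between samples, and the planned median-of-ratios rescaling was void as a check. The depth set the precision of low genes: at these totals Src had 26 to 52 reads per sample and Ldha 21067 to 29195. PCR copies cannot be told from separate molecules in these values.

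The gene identifiers belong to the gene set of the C57BL/6NJ strain. The submitters' processing notes name GRCm38 and mm10, yet of 29735 gene names shared with a GENCODE annotation of GRCm38, 29686 were on the same chromosome and 0 had the same start. Positions are therefore printed as the table gives them, and the build behind them is not named by a source used here. The table holds chromosomes 1 to 19 and X, so Y-linked and mitochondrially encoded genes were not analysed here. Gene names came from the table's name column (30409 genes) and, for 328 further genes, from the UniProt match in the table's own description, among them Fpr2, C4b and Naip1. A total of 52 repeated names were kept on 1 row each, and 23 names read as dates, the form a spreadsheet gives to septin and MARCH family names, and were left as they stand.

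The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit and eBayes (trend and robust moderation), for genes with FPKM of at least 1 in at least 4 samples, over all 9 samples with group as the only factor. The tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Since the unit was FPKM, the count test that the design foresaw for a count table was not used. Lists of genes were compared with the other genes by camera (preset correlation 0.01), over lists with at least 5 tested genes, and again with an estimated correlation, on ranks, and with fry, which asks whether a list moves one way or, in its mixed form, in either way, without comparing it with other genes. Of 50 lists, 15 hold markers of cell types that an exudate can contain, and 44 were tested. The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. For Apoe, Gpr132, Src and Ldha an exact two-sided permutation test over the 126 splits of the samples into 5 and 4 was added, since Src lay under the filter.

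The rule for named genes takes Apoe first, then Gpr132, Src and Ldha, which the series' subject names, then the 10 largest rises and 10 largest falls among passing genes. It leaves out predicted genes, pseudogenes and antigen receptor segments. From each list it takes up to 4 passing genes in order of p or, where none passes, up to 2 with the smallest p, given as values only. Other genes are said to have been chosen after their values were seen. Genes with close copies, such as the tryptases Tpsb2 and Tpsab1, the alpha globins, C4b, the ribosomal proteins with their pseudogenes and the antigen receptor genes, are uncertain because the counting may split or share their reads.

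The fit was tested on simulated data. Reads drawn with the means, the library sizes and the spread within groups of the real genes, and with 100 genes changed 2-fold and 100 changed 4-fold, gave back 80 of the former and 95 of the latter among 11183 genes tested for the simulated comparison of diabetic with control. Of the 184 genes called there, 9 were unchanged, and 0 of 20 random lists were called. The changed genes were not drawn from the lowest expressed ones. Each gene was drawn independently of the others, so the random lists cannot test list calls among genes that vary together, as those of the real lists do. Libraries of the same group were compared for duplicates, and the chi-square over its degrees of freedom ranged from 12.7 to 69.8, so none was counted as a copy of another. The alternatives were pseudocounts of 0.1 and 0.01, no filter or FPKM of at least 0.1 or 5 in 4 samples, TPM rescaling, median-of-ratios scaling, quantile normalization, no trend or robust moderation, array weights, the replicate number as a block over the 8 samples whose number both groups share, and leaving out each sample in turn. After the data were seen, plain library totals, limma voom on the recovered reads, names from the name column alone and permutation fits for Src were added. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.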

Results

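Cells rinsed from the peritoneal cavity of Apoe-deficient mice on a western diet were profiled by RNA sequencing in 5 control samples and 4 diabetic samples, 3 days after a thioglycollate injection. The series concerns how diabetes changes macrophages in atherosclerosis, with lactate, the receptor GPR132 and the kinase Src in its title. The only comparison its design implies is diabetic against control. Each library held 14156421 to 16169060 reads in genes. Between 10658 and 11219 genes per sample reached an FPKM of 1. Group and sample structure overlapped in part. The first principal component (36.0% of the variance) placed the 5 control samples between -23.5 and -11.2, diabetic 1, 2 and 4 between 20.9 and 30.5, and diabetic 3 between them at 1.44.

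Apoe, the disrupted gene, was measured first in every sample. It stood at 231, 373, 286, 262 and 238 FPKM in control 1 to 5 and at 282, 296, 213 and 135 FPKM in diabetic 1 to 4 (log2 fold change -0.30, SE 0.23, adjusted p = 0.47). The gene's reads did not differ beyond the spread between samples. A summed value per gene can come from RNA of a disrupted locus, and the series has no wild-type sample to set beside it. These values check neither the genotype nor the labels.

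**Figure D1:**
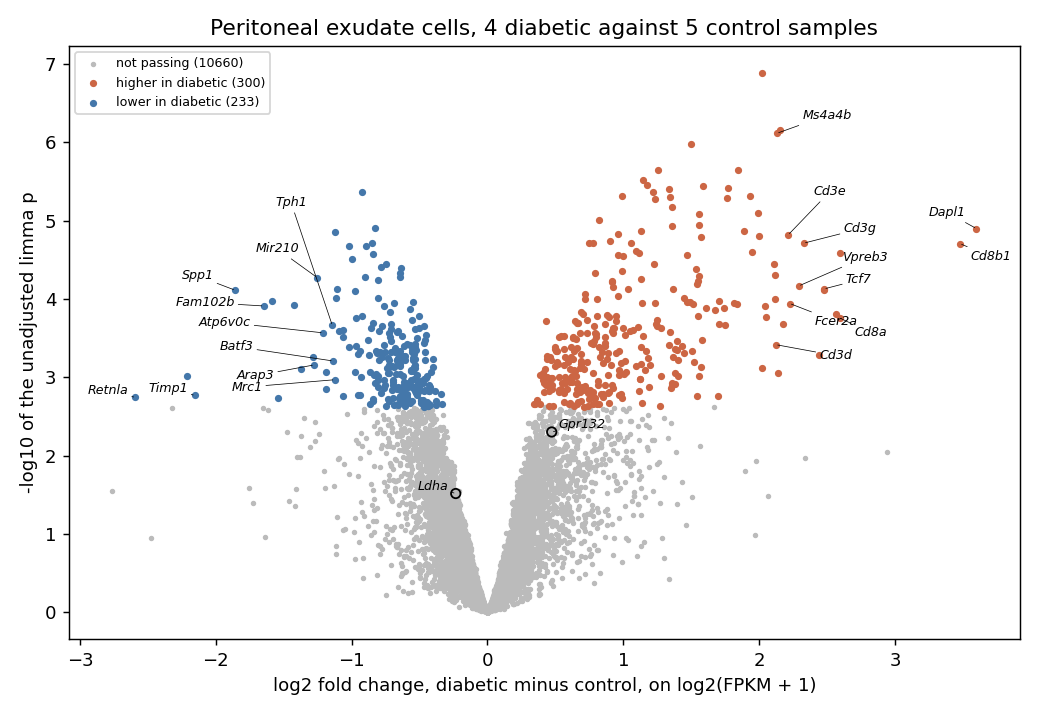
Each point is 1 of 11193 genes, with the log2 fold change (diabetic minus control, on log2(FPKM + 1)) on the x axis and -log10 of the unadjusted limma p on the y axis. The 300 genes higher in diabetic samples reach 3.60 (Dapl1) and the 233 lower ones -2.59 (Retnla), and the circled Gpr132 and Ldha lie among the genes that did not pass.

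Of 11193 genes tested, 533 changed, 300 higher and 233 lower in diabetic samples. Of these, 123 of the rises against 27 of the falls reached a log2 fold change of 1. The 10 largest rises were Dapl1, Cd8b1, Cd8a, Tcf7, Cd3g, Vpreb3, Fcer2a, Cd3e, Ms4a4b and Cd3d. Cd8b1, a chain of the CD8 co-receptor of cytotoxic T cells, had 3.94 ± 1.73 FPKM in control (SD, n = 5) and 62.0 ± 37.1 in diabetic samples (SD, n = 4) (log2 fold change 3.48, SE 0.45, adjusted p = 0.0055). Dapl1, which naive T cells express, had 1.33 ± 0.614 against 31.9 ± 20.2 FPKM (log2 fold change 3.60, SE 0.45, adjusted p = 0.0054). Tcf7, the transcription factor TCF-1 of naive and memory T cells, had 4.57 ± 1.04 against 34.1 ± 17.3 FPKM (log2 fold change 2.48, SE 0.38, adjusted p = 0.011). Vpreb3 and Fcer2a, both B lineage genes, rose with log2 fold changes of 2.29 and 2.23. The rises of Dapl1, Cd8b1, Tcf7, Cd3g, Vpreb3, Cd3e and Ms4a4b passed in all 9 fits that left out 1 sample.

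The 10 largest falls were Retnla, Timp1, Spp1, Fam102b, Arap3, Mir210, Atp6v0c, Tph1, Batf3 and Mrc1. Spp1, which encodes the matrix and cytokine protein osteopontin, fell from 538 ± 129 FPKM (SD, n = 5) to 157 ± 75.5 (SD, n = 4; log2 fold change -1.86, SE 0.29, adjusted p = 0.011). Its 4 diabetic values (86.3 to 261 FPKM) all lay below its 5 control values (401 to 707 FPKM). Retnla, a marker of alternatively activated macrophages, had 1512 ± 1789 against 174 ± 60.4 FPKM (log2 fold change -2.59, SE 0.61, adjusted p = 0.043). Control 2 stood at 4683 FPKM and the other control samples at 478 to 1097 FPKM. Timp1, an inhibitor of matrix metalloproteinases, had 41.4 ± 28.0 against 6.63 ± 0.967 FPKM (log2 fold change -2.15, SE 0.50, adjusted p = 0.041). Mrc1, the mannose receptor CD206, had 52.6 ± 12.4 against 24.5 ± 11.1 FPKM (log2 fold change -1.13, SE 0.25, adjusted p = 0.033). Batf3, a transcription factor of cross-presenting dendritic cells, had 26.0 ± 4.89 against 11.7 ± 4.43 FPKM (log2 fold change -1.14, SE 0.24, adjusted p = 0.025). The Mir210 row, 110 bases around a microRNA, rests on 14 reads over the control libraries and 1 over the diabetic libraries. The Atp6v0c row rests on 161 and 31 reads. Of these falls, Spp1, Fam102b and Mir210 passed in all 9 fits that left out 1 sample, and Atp6v0c and Tph1 in 7. Retnla, Arap3 and Batf3 passed in 3 of the 9 fits, Timp1 in 2 and Mrc1 in 1.

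Groups that did not overlap were found for 1054 genes, 9.42% of those tested against 1.59% by chance. They include 487 of the 533 changed genes. The count of changed genes depended on single libraries. It was 115 without diabetic 4, 119 without diabetic 2, 198 without control 3, 230 without diabetic 1, 325 without control 1, 352 without control 4 and 1126 without diabetic 3.

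T cell genes made the clearest group. Of 22 tested T cell markers, 20 were higher in diabetic samples and 0 lower, with a median log2 fold change of 2.08 (adjusted p = 2.7e-23 by camera with the preset correlation and adjusted p = 0.67 with an estimated correlation; unadjusted p = 0.015 for the latter). Cd3e and Cd3g, parts of the T cell receptor complex, had 2.69 ± 0.593 against 17.4 ± 7.82 FPKM (log2 fold change 2.21, SE 0.29, adjusted p = 0.0055) and 8.03 ± 2.02 against 47.8 ± 22.5 FPKM (log2 fold change 2.33, SE 0.31, adjusted p = 0.0055). Thy1 rose from 13.5 ± 2.12 to 60.6 ± 23.8 FPKM (adjusted p = 0.0055). Cd4 rose as well, by less (log2 fold change 1.55, SE 0.24, adjusted p = 0.010; chosen after its values were seen). Counted relative to the control mean of the list's mean log2(FPKM + 1), the 4 diabetic samples lay 1.73, 2.41, 0.91 and 2.24 above it, and the control samples between -0.16 and 0.25.

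B cell genes rose in part. Of 23 tested B cell markers, 6 were higher and 0 lower, with a median log2 fold change of 0.63 (adjusted p = 7.6e-08 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). A total of 9 passed when adjusted over the list alone. Ighd, the constant region of IgD, had 35.6 ± 9.98 FPKM in control (SD, n = 5) and 221 ± 103 in diabetic samples (SD, n = 4) (log2 fold change 2.48, SE 0.38, adjusted p = 0.011). Fcmr, the IgM Fc receptor, had 32.7 ± 8.50 against 99.4 ± 29.6 FPKM (log2 fold change 1.55, SE 0.24, adjusted p = 0.0097). Fcer2a, the low-affinity IgE receptor CD23 of follicular B cells, had 3.85 ± 1.02 against 24.2 ± 12.6 FPKM. Cd5 (log2 fold change 1.68, SE 0.28, adjusted p = 0.014) is on the T cell list too. The general B lineage genes Ms4a1 and Cd79a did not pass. Their log2 fold changes were 0.31 and 0.47 (adjusted p = 0.64 and 0.42; chosen after their values were seen). Diabetic 3 (0.14 above the control mean of the B cell list) lay within the range of the control samples (-0.54 to 0.33). Of 12 natural killer cell markers 1 rose, Klrd1 (log2 fold change 1.13, SE 0.19, adjusted p = 0.013). The list was called higher (adjusted p = 0.025 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation). The call ended without control 1, control 2, diabetic 1, diabetic 3 or diabetic 4 (highest adjusted p = 0.25), and the mean log2 fold change of 0.31 became 0.18 without diabetic 3 and 0.49 without diabetic 2.

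**Figure D2:**
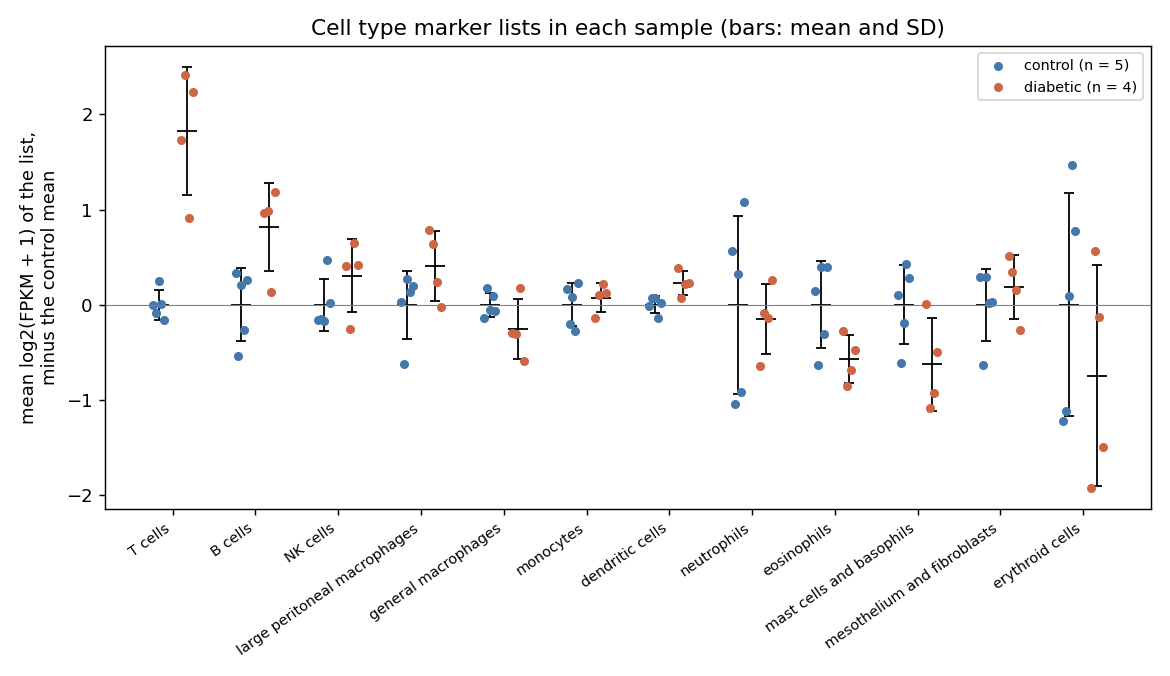
Mean log2(FPKM + 1) of each marker list in each sample, minus the mean of the 5 control samples (y axis), for 12 lists (x axis), with control samples in blue and diabetic samples in orange and bars for the mean and SD. The 4 diabetic samples lie at 0.91 to 2.41 for T cells, while for neutrophils the control samples spread from -1.04 to 1.07.

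Of 19 markers of large peritoneal macrophages, the resident population of the cavity, 18 had a positive log2 fold change (median 0.38; adjusted p = 0.0041 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Only Naip1 passed (log2 fold change 0.56, SE 0.14, adjusted p = 0.047; named from a UniProt match), and 5 were higher and 1 lower when adjusted over the list alone. The mean log2 fold change of the list was 0.41, and 0.25 without control 2 (adjusted p = 0.032), whose list mean of 3.98 lay under the 4.63 to 4.87 of the other control samples. Relative to the control mean, diabetic 3 (0.24) and diabetic 4 (-0.026) lay within the control range of this list (-0.62 to 0.27). Of 14 general macrophage markers 12 had a negative log2 fold change (median -0.21; adjusted p = 0.025 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation). Only Mrc1 passed. Diabetic 3 (0.17) lay within the control range of the general list (-0.14 to 0.18), and the mean log2 fold change of the list ran from -0.40 to -0.14 over the fits that left out 1 sample. The general macrophage call ended without control 2, control 4, diabetic 1 or diabetic 4 (highest adjusted p = 0.27). The 15 monocyte markers were not called as a list (camera adjusted p = 0.60).

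Mast cell and basophil markers were lower as a list, all 9 with negative log2 fold changes (median -0.54; adjusted p = 0.0074 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation). No single gene passed over all genes and 2 did over the list alone. The tryptase Tpsb2 had 199 ± 72.1 against 70.5 ± 44.1 FPKM (log2 fold change -1.62, SE 0.40, adjusted p = 0.053). The mast cell call ended without diabetic 3 (adjusted p = 0.069). Relative to the control mean of this list, diabetic 1 (0.0080) and diabetic 4 (-0.50) lay within the control range (-0.61 to 0.42). The 6 eosinophil markers (median -0.86; camera adjusted p = 0.068) and the 14 neutrophil markers (median -0.17; camera adjusted p = 0.60) were not called. Without control 2 the eosinophil list was called lower (camera adjusted p = 0.013). Cebpe, a granulocyte transcription factor, had 28.7 ± 14.7 against 7.80 ± 3.00 FPKM (log2 fold change -1.65, SE 0.41, adjusted p = 0.052). Alox15 had 22.9 ± 7.43 against 64.4 ± 35.4 FPKM (log2 fold change 1.35, SE 0.36, adjusted p = 0.062). In the neutrophil list Stfa3 and Padi4 had log2 fold changes of 0.62 and -0.22.

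Dendritic cell markers included 2 rises and 1 fall among 10 tested (camera adjusted p = 0.12). Ccr7, the homing receptor of migratory dendritic cells and naive T cells, had 32.2 ± 5.09 against 135 ± 50.1 FPKM (log2 fold change 1.95, SE 0.27, adjusted p = 0.0063). Dpp4 had a log2 fold change of 0.70, and Batf3 fell by 1.14. Mesothelial and fibroblast markers were not called (camera adjusted p = 0.19; Upk1b 0.59 and Msln 0.37), nor were 6 erythroid markers (camera adjusted p = 0.45). The alpha globin Hba-a1 had 66.3 ± 57.9 against 10.7 ± 13.4 FPKM (log2 fold change -2.76, SE 1.07, adjusted p = 0.17). Too few genes of the adipocyte, endothelial and platelet lists were tested for a list test. Pnpla2 and Lipe of the adipocyte list had log2 fold changes of 0.14 and -0.083. Of 12 endothelial list genes only Pecam1, which is on the receptor and adhesion list too, was tested. It rose (log2 fold change 1.12, SE 0.26, adjusted p = 0.038) and passed in 3 of the 9 fits that left out 1 sample. A rise of 1 such gene does not show a rise of endothelial RNA. The platelet gene Treml1 fell (log2 fold change -1.07, SE 0.20, adjusted p = 0.019; 202 reads over the control and 39 over the diabetic libraries).

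The genes of the series' subject came next. Gpr132, a G protein-coupled receptor linked to lactate sensing in macrophages (chromosome 12, 118889031 to 118899188, identifier MGP_C57BL6NJ_G0020549), had 26.5 ± 3.71 FPKM in control (SD, n = 5) and 37.3 ± 5.82 in diabetic samples (SD, n = 4). Its log2 fold change was 0.47 (SE 0.13), and it did not pass over all genes (adjusted p = 0.073). The exact two-sided permutation test of this gene gave p = 0.032 (adjusted p = 0.063 over the 4 genes tested this way). All 4 diabetic samples lay above the control mean, diabetic 3 the lowest of them at 29.5 FPKM, below control 5 at 31.7 FPKM. Without diabetic 3 the gene passed (log2 fold change 0.58, adjusted p = 0.019; adjusted p = 0.019 to 0.20 over all alternatives), and with array weights as well (adjusted p = 0.023). Gpr65, of the acid and lactate receptor list, had 18.1 ± 4.56 against 22.2 ± 7.25 FPKM (log2 fold change 0.26, SE 0.22, adjusted p = 0.54; chosen after its values were seen).

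**Figure D3:**
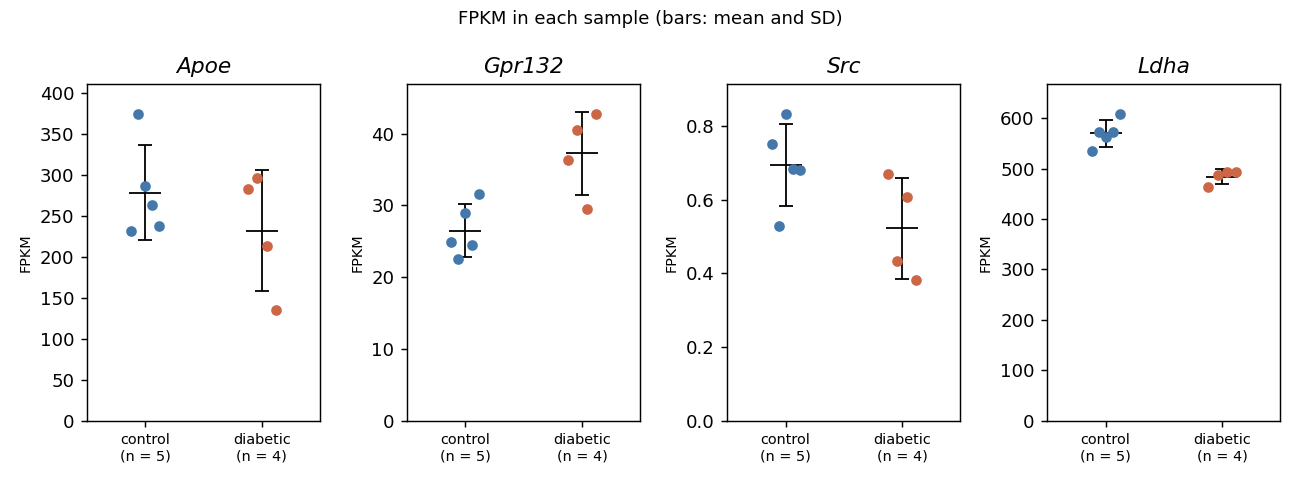
FPKM (y axes, from 0) of Apoe, Gpr132, Src and Ldha in each of 5 control samples (blue) and 4 diabetic samples (orange), with bars for the mean and SD. Ldha of the diabetic samples (463 to 494 FPKM) lies below every control sample (535 to 608 FPKM), whereas Gpr132 of diabetic 3 lies within the control range.

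Src itself (chromosome 2, 167257388 to 167313295, identifier MGP_C57BL6NJ_G0027206) was low, at 0.695 ± 0.112 FPKM in control (SD, n = 5) and 0.523 ± 0.137 in diabetic samples (SD, n = 4), from 26 to 52 reads per sample. It stayed under the filter of the fit. Its log2 difference was -0.16 (exact two-sided permutation p = 0.095, adjusted p = 0.13 over 4 genes). Over 12 alternatives it ran from -0.43 (pseudocount 0.01) to -0.11 (without diabetic 4), and without control 2 it was -0.19 (exact p = 0.029). Of 12 Src family kinases and regulators, only Lck, the family member of T cells, rose (log2 fold change 2.12, SE 0.34, adjusted p = 0.013). The list was not called (camera adjusted p = 0.40). RNA levels say nothing of kinase activity.

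Glycolysis genes were lower in diabetic samples. Of 18 tested, 14 had negative log2 fold changes (median -0.25; adjusted p = 0.0020 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Of them 2 passed over all genes and 7 when adjusted over the list alone. Tpi1, triose phosphate isomerase, had 279 ± 29.6 against 192 ± 7.46 FPKM (log2 fold change -0.53, SE 0.11, adjusted p = 0.022). Pfkfb4, a regulator of glycolytic flux, had 14.3 ± 2.49 against 9.18 ± 1.82 FPKM (log2 fold change -0.59, SE 0.15, adjusted p = 0.045). Of the 9 fits that left out 1 sample, Tpi1 passed in 5 and Pfkfb4 in 1. Ldha, the lactate dehydrogenase subunit that makes lactate (chromosome 7, 49511849 to 49525997, identifier MGP_C57BL6NJ_G0032755), had 569.7 ± 26.2 against 484 ± 14.4 FPKM (log2 fold change -0.23, SE 0.094, adjusted p = 0.17). Its exact two-sided permutation p was 0.0079, the smallest that the 126 splits can give (adjusted p = 0.032 over 4 genes), with 4 of 4 diabetic samples lower. Groups that did not overlap, as for Ldha, were found for 9.42% of all genes tested, so this p does not single the gene out. Over all genes Ldha passed in 0 of 22 alternatives. The 15 lactate handling genes were not called (camera adjusted p = 0.81). Slc16a3, the lactate exporter MCT4, had 73.8 ± 22.7 against 43.4 ± 4.28 FPKM (log2 fold change -0.71, SE 0.19, adjusted p = 0.062). Mpc1, a mitochondrial pyruvate carrier, had 8.62 ± 3.45 against 13.8 ± 1.88 FPKM (log2 fold change 0.69, SE 0.24, adjusted p = 0.13). The mean of the glycolysis list in each of the 4 diabetic samples (4.62 to 4.70) lay below every control sample (4.76 to 5.09). The T cell list moved the other way in the same samples.

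Tkt (log2 fold change -0.44, SE 0.10, adjusted p = 0.031) and Pgd (log2 fold change -0.43, SE 0.10, adjusted p = 0.037) were the passing members of 25 oxidative stress genes. The list was called lower (adjusted p = 0.024 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). The preset call ended without control 5, diabetic 1 or diabetic 4 (highest adjusted p = 0.13). Among 19 glucose and insulin responsive genes Foxo1 rose (log2 fold change 0.79, SE 0.15, adjusted p = 0.019) and Akr1b8 (log2 fold change -0.82, SE 0.17, adjusted p = 0.023) and Tkt fell. Camera did not call this list (adjusted p = 0.22), while fry did (adjusted p = 0.048). Oxidative phosphorylation genes were called lower with small changes, 36 of 49 negative (median -0.083; adjusted p = 0.039 by camera with the preset correlation and adjusted p = 0.80 with an estimated correlation). None of them passed alone (Atp5j -0.54, Uqcrq -0.45). The list call ended without control 2, control 4, diabetic 1, diabetic 3 or diabetic 4 (highest adjusted p = 0.49). The mean log2 fold change of -0.11 became -0.039 without control 2. The 17 citrate cycle genes (Fh1 0.24, Suclg1 0.21; camera adjusted p = 0.60) and 21 hypoxia genes (Slc2a1 -0.56, P4ha1 -0.33; camera adjusted p = 0.25) were not called.

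Interferon stimulated genes were higher in diabetic samples, 31 of 34 with positive log2 fold changes and 6 passing (median 0.56; adjusted p = 3.2e-10 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). A total of 21 passed when adjusted over the list alone. Ifi47, an interferon-induced GTPase, had 28.6 ± 4.92 against 69.4 ± 9.57 FPKM (log2 fold change 1.26, SE 0.14, adjusted p = 0.0033). Zbp1, a nucleic acid sensor, had 14.7 ± 2.51 against 37.8 ± 12.9 FPKM (log2 fold change 1.25, SE 0.23, adjusted p = 0.018). Xaf1 had a log2 fold change of 0.84. The rise was uneven. The list means of diabetic 1, 3 and 4 were 4.03, 4.27 and 3.97. That of diabetic 2, at 3.39, lay within the control range of 3.07 to 3.55. Diabetic 3, with the highest interferon mean, had the lowest T cell mean of the 4, and diabetic 2 the highest. Antigen presentation by MHC class I was called higher (adjusted p = 0.013 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Of 13 genes Nlrc5, its transactivator (log2 fold change 0.82, SE 0.11, adjusted p = 0.0050), and Tap1, the peptide transporter (log2 fold change 0.63, SE 0.12, adjusted p = 0.019), passed. This call ended without diabetic 3 (adjusted p = 0.074). Of 14 MHC class II genes only H2-Oa, which B cells express, rose (log2 fold change 1.06, SE 0.15, adjusted p = 0.0055; list camera adjusted p = 0.34).

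Alternative activation genes included the falls of Retnla, Mrc1 and Egr2 (log2 fold change -0.87, SE 0.18, adjusted p = 0.024) among 22 tested and no rise. The list was not called (camera adjusted p = 0.13). Matrix remodelling genes were called lower (adjusted p = 0.022 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Of 21 genes 16 were negative, 3 passing, and 1 higher and 6 lower when adjusted over the list alone. The matrix metalloproteinase Mmp19 had 37.9 ± 4.66 against 18.3 ± 3.60 FPKM (log2 fold change -1.02, SE 0.14, adjusted p = 0.0056), beside Spp1 and Timp1. The list call ended without control 4 (adjusted p = 0.053) or diabetic 4 (adjusted p = 0.054). Egr2 was also the passing member of 22 immediate early and heat shock genes. The list was called lower (adjusted p = 0.024 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation) except without control 1, control 3 or control 5 (highest adjusted p = 0.089).

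Lipid genes were mostly lower. Of 21 lipid uptake and storage genes 18 had negative log2 fold changes (median -0.31; adjusted p = 0.013 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Only Spp1 passed, and the call ended without diabetic 4 (adjusted p = 0.11). Cholesterol synthesis genes were called lower, 17 of 19 negative (median -0.23; adjusted p = 0.0041 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation). The mean log2 fold change of the list was -0.25, and -0.14 without control 2 (adjusted p = 0.046), whose list mean of 3.40 lay over the 2.76 to 2.89 of the other control samples. Lysosome genes were called lower, 33 of 35 negative (median -0.22; adjusted p = 0.0035 by camera with the preset correlation and adjusted p = 0.78 with an estimated correlation). None of them passed alone (Mcoln1 -0.40, Tfeb -0.35), and the list was not called without diabetic 4 (adjusted p = 0.13). Its mean log2 fold change of -0.23 became -0.13 without diabetic 4 and -0.14 without control 2. Among the diabetic samples the lysosome mean was highest in diabetic 3 (7.53) and lowest in diabetic 4 (6.89). The general macrophage markers, with a median log2 fold change of -0.21, had the same order there (8.39 and 7.63). Whether a smaller part of macrophage RNA lowered the lysosome list was not tested. Of 18 cholesterol efflux genes Mylip, a ubiquitin ligase of cholesterol handling, rose (log2 fold change 0.69, SE 0.17, adjusted p = 0.046). The list was not called (camera adjusted p = 0.23). The fatty acid synthesis genes Scd1 and Scd2 had log2 fold changes of 0.97 (adjusted p = 0.061) and 0.69 (list camera adjusted p = 0.60). The fatty acid oxidation genes Etfb and Acot1 had -0.38 and -0.37 (list camera adjusted p = 0.22).

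**Figure D4:**
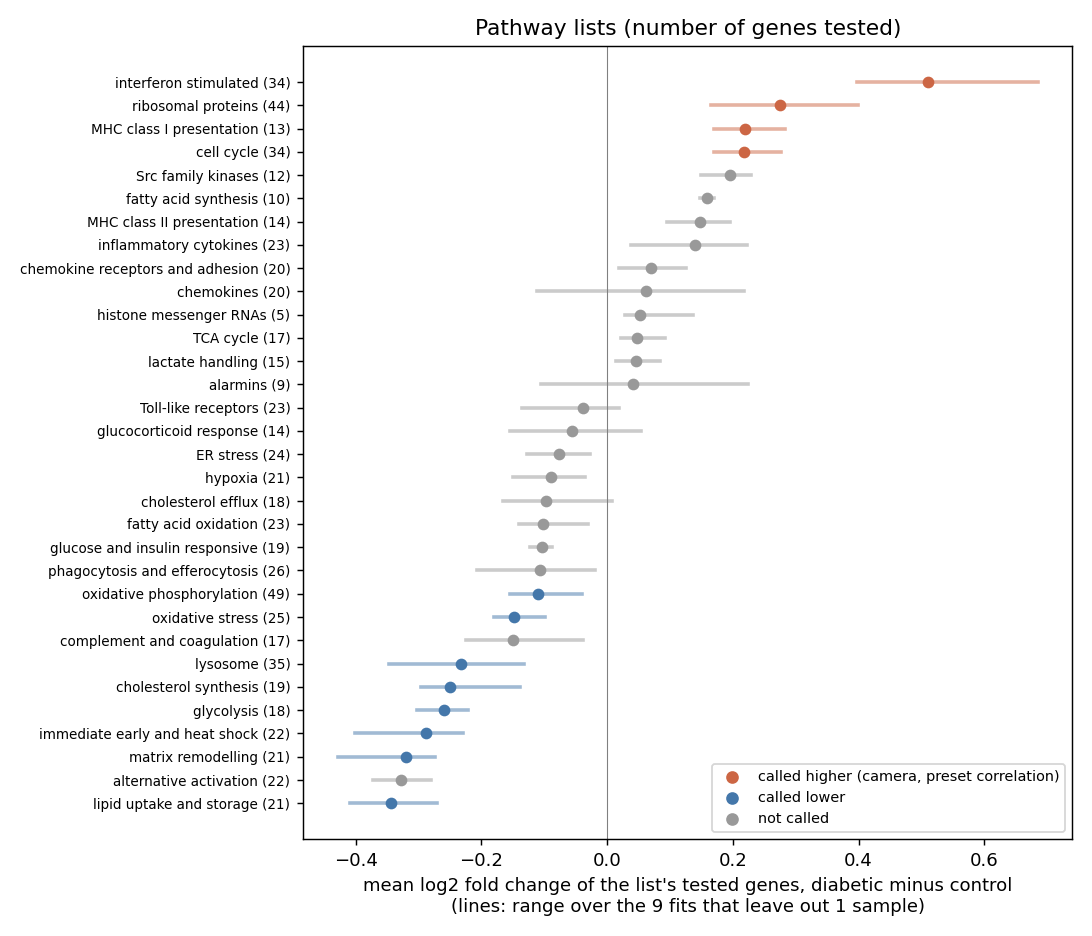
Mean log2 fold change (x axis, diabetic minus control) of the tested genes of each pathway list (y axis, number of genes in brackets), with lines for the range over the 9 fits that leave out 1 sample. Interferon stimulated genes stand highest at 0.51 and lipid uptake and storage genes lowest at -0.34, and colours mark calls by camera with the preset correlation.

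Ribosomal protein genes were called higher, 41 of 44 positive (median 0.25; adjusted p = 3.9e-07 by camera with the preset correlation and adjusted p = 0.74 with an estimated correlation). The mean log2 fold change of the list was 0.27, and 0.16 without diabetic 2. Rpl5 (log2 fold change 0.73, SE 0.14, adjusted p = 0.019), Rpl22, Rps7 and Rps23 passed. All genes with names of the ribosomal protein form, a wider set than the list, took 8.46%, 10.7%, 6.63% and 10.00% of the reads in diabetic 1 to 4. In control samples they took 6.67% to 7.61%. Diabetic 3, with the lowest T cell mean of the diabetic samples, was barely under that control range. On the tested list its mean of 8.82 lay within the control range (8.78 to 9.04). Cell cycle genes were called higher, 32 of 34 positive (median 0.20; adjusted p = 7.1e-05 by camera with the preset correlation and adjusted p = 0.69 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was the gene that passed (log2 fold change 0.72, SE 0.12, adjusted p = 0.013).

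The remaining lists were not called. Among inflammatory genes Traf1 (0.51) and Nfkbia (0.48) rose (list camera adjusted p = 0.099). Of the 9 fits that left out 1 sample, Traf1 passed in 5 and Nfkbia in 2. Without control 5 or diabetic 2 the inflammatory list was called (lowest camera adjusted p = 0.022). Its mean log2 fold change of 0.14 ran from 0.037 to 0.22 over these fits. Among 20 chemokines Ccl5, which T and natural killer cells also make, rose (log2 fold change 0.94, SE 0.17, adjusted p = 0.017; list camera adjusted p = 0.53). Among receptors and adhesion genes Fpr2 (0.88) and Pecam1 rose (list camera adjusted p = 0.81). Fcgr4, an activating Fc receptor, rose (log2 fold change 0.97, SE 0.21, adjusted p = 0.029), and the integrin chain Itgb5 fell (log2 fold change -0.71, SE 0.13, adjusted p = 0.018) in the phagocytosis list (camera adjusted p = 0.15). Tlr8 fell (log2 fold change -1.09, SE 0.21, adjusted p = 0.018) while Nod1 (0.57) and Tmem173, the sensor adaptor STING (0.46), rose among 23 Toll-like and related receptors (camera adjusted p = 0.93). S100a6 fell among 9 alarmins (log2 fold change -0.46, SE 0.11, adjusted p = 0.038; list camera adjusted p = 0.60). Complement and coagulation genes (C4b 1.19, F5 -0.92; camera adjusted p = 0.13), glucocorticoid response genes (Tsc22d3 0.41, Nr3c1 -0.30; camera adjusted p = 0.73), endoplasmic reticulum stress genes (Hsp90b1 -0.47, Eif2ak3 0.39; camera adjusted p = 0.40) and 5 histone genes (Hist1h2ae 0.65, Hist1h1c -0.36; camera adjusted p = 0.98) had no passing member. Median, mean or test differed in sign for lactate handling, chemokines, chemokine receptors and adhesion, fatty acid synthesis, alarmins, Toll-like receptors and histones.

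Across lists, 18 of 44 were called with the preset correlation, 8 higher and 10 lower, 18 on ranks and 0 with an estimated correlation. Fry called 4 lists moving one way and 25 changing in either direction. The 4 were T cells (fry adjusted p = 0.013), glycolysis, dendritic cells and glucose and insulin responsive genes (fry adjusted p = 0.048 each). Of these, camera called T cells and glycolysis only, so the other lists that camera called were not called one way by fry. At an unadjusted p under 0.05 limma gave 2511 genes.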

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

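Samples far from the rest of their group were sought by the gap to the nearest sample over the group's range, in 360 groups of values, of which 15 (4.17%) stood out where chance gives about 5%. The tests of blood in the lavage and of Gpr132 with lymphocyte genes were chosen after those values were seen, as were the genes Cxcr3, Dok2, Gsn and Ighv11-2.

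On the log2(FPKM + 1) scale, diabetic 3 stood apart in 5 genes: Mpc1 at 4.14 (others 3.77 to 3.81), Eif2ak3 at 3.28 (3.76 to 3.84), Cxcr3 at 2.77 (2.87 to 2.89), Dok2 at 6.63 (6.39 to 6.42) and Gsn at 6.52 (5.93 to 6.01). Control 2 stood apart for Suclg1 at 4.25 (others 3.84 to 3.89), for Treml1 at 1.02 (1.67 to 1.90), for the mean of the cholesterol synthesis genes at 3.40 (2.76 to 2.89) and for the mean of the large peritoneal macrophage markers at 3.98 (4.63 to 4.87). Control 5 stood apart for Mcoln1 at 4.25 (others 4.54 to 4.65) and Msln at 0.72 (1.25 to 1.39), and control 3 for Tsc22d3 at 7.21 (7.32 to 7.35) and Ighv11-2 at 5.45 (3.14 to 3.34). Diabetic 4 stood apart for the mean of the fatty acid oxidation genes at 3.65 (others 3.85 to 3.85). Diabetic 1 stood apart for Mir210 at 0.66, which is 1 read, against 0 in the other diabetic samples.

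The rise of T and B cell genes was weighed first. A lower share of macrophages would raise the markers of every other cell type alike. The 44 T and B cell markers had a median log2 fold change 1.21 above that of 61 markers of other cell types (bootstrap 95% interval 0.83 to 1.89). The bootstrap drew genes with the samples held fixed, so it leaves out the spread between samples and counts markers that vary together as separate. In these samples the gap argues against a lower macrophage share as the whole cause. The rise did not depend on the scaling, since the lowest T cell median over TPM, plain totals and quantile normalization was 2.07, and blood in the lavage would bring red cells, while Hba-a1 had a log2 fold change of -2.76 (95% interval -5.16 to -0.36), below the T cell median of 2.08. A larger share of lymphocytes, above all T cells, in the exudate of diabetic mice may explain the rise as a hypothesis. Cell counts were not analysed here, lymphoid tissue caught in the rinse and unrecorded collection days were not tested, and the alpha globins share reads with a near copy.

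The genes lower in diabetic samples were weighed next. The median of general macrophage markers lay 0.44 above that of the 233 lower genes (bootstrap 95% interval 0.34 to 0.53; medians -0.21 and -0.65), but the lower genes were selected for their fall, which fixes the sign of this gap, so it says nothing about dilution of macrophage RNA by lymphocyte RNA. Fewer resident large peritoneal macrophages would lower their markers, whose median was 0.38 (bootstrap 95% interval 0.20 to 0.66). These bootstraps too drew genes and not samples. Diabetic 3 (0.24) and diabetic 4 (-0.026) lay within the control range of the large peritoneal macrophage list (-0.62 to 0.27). Dilution and a change of state of the elicited macrophages in diabetes both stay open.

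Gpr132 was weighed last. With the mean of the T and B cell lists as a covariate, its group difference of 0.47 became -0.095 (95% interval -0.55 to 0.36), and within the groups Gpr132 followed that mean (slope 0.44 log2 units per unit, exact permutation p = 0.0083 over 2880 reorderings). These values are consistent with RNA from more T and B cells as the source of the higher Gpr132, since lymphocytes express the gene too. The covariate also separates the groups and left 7 genes changed in all, so a rise within macrophages in diabetes stays open.

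Chance in how the samples were grouped was tested by refitting 100 of the 126 splits of the 9 samples into 5 and 4. Only 1 split, the real one, gave as many as its 533 changed genes, and the highest of the others gave 2, which argues against chance as the source of the count.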

How the results depend on the processing

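Plain totals, voom, names from the name column alone (all list calls unchanged) and the Src fits were chosen after the data were seen. Against 533 changed genes (300 higher, 233 lower), no filter gave 183 (129 and 54) among 22471 genes, array weights 1304 (677 and 627). The replicate block, fitted on 8 samples since control 5 has no partner, gave 73 (52 and 21), against 363 (216 and 147) without control 5 and no block. Fits without 1 sample gave 115 to 1126 changed, 71 to 584 higher, 35 to 542 lower and 12 to 19 lists. FPKM of at least 5 gave 372 (187 and 185) and 12 lists. The other gene-level alternatives gave 488 to 655 changed genes and 14 to 20 lists. An estimated correlation ended all 18 list calls (0 of 44). Higher genes made up 56.3% of the 533, 48.9% under TPM and 70.5% without a filter. The median of all genes moved by under 0.1 under each scaling, and median-of-ratios scaling moved almost nothing (534 genes). Same-numbered samples share only a number: the correlations of their deviations were 0.02, 0.16, -0.26 and -0.18, and only diabetic 2 correlated best with its own number.

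Of 88 named genes called with all 9 samples, 28 passed in all 9 fits without 1 sample. The number lost was 54 without diabetic 4, 53 without diabetic 2, 42 without control 3, 40 without diabetic 1, 27 without control 4, 23 without control 1, 19 without control 5, 14 without control 2 and 1 without diabetic 3. No named gene changed sign. Mean log2 fold changes of 9 uncalled lists did: histones -0.017 without a filter, -0.028 with FPKM of at least 0.1 and -0.028 under TPM; alarmins -0.00241 under TPM; and with array weights alarmins -0.25, chemokines -0.0669, chemokine receptors and adhesion -0.030 and monocytes -0.060. Without 1 sample, neutrophils reached 0.13 (control 5 left out, the same with the block on those 8 samples, and positive too without control 1 or diabetic 1, lowest -0.41), alarmins -0.11 (control 2 left out, and negative too without control 4, diabetic 2 or diabetic 4, highest 0.22), chemokines -0.11 (control 2 left out, highest 0.22), Toll-like receptors 0.019 (diabetic 1 left out, lowest -0.13), cholesterol efflux 0.0073 (diabetic 4 left out, lowest -0.17) and glucocorticoid response 0.053 (diabetic 4 left out, lowest -0.15). The causes were not tested. Count tools that the design named for a count table were not run.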

Other observations

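All genes and tests in this part were chosen after the values were seen. Beyond the fixed lists, Zap70 (log2 fold change 1.51, SE 0.25, adjusted p = 0.013), a kinase of T cell receptor signalling, rose in diabetic samples, and of 8 tested Gimap genes, GTPases of lymphocyte survival, 4 were higher and all 8 had positive log2 fold changes (median 1.15), for example Gimap6 at 26.8 ± 3.68 against 76.1 ± 29.4 FPKM. Of 14 tested T cell receptor beta variable genes 10 were higher. Picked because they rose, 4 further genes were Nkg7 (log2 fold change 1.27, SE 0.23, adjusted p = 0.018), Cxcr3 (log2 fold change 0.75, SE 0.10, adjusted p = 0.0055), Irf1 (log2 fold change 0.77, SE 0.11, adjusted p = 0.0055) and the GTPase Igtp (log2 fold change 1.17, SE 0.14, adjusted p = 0.0033).

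The difference of log2(FPKM + 1) between Cd8b1 and Cd4, taken within each sample, was 0.86 ± 0.35 in control (SD, n = 5) and 2.79 ± 0.48 in diabetic samples (SD, n = 4). For Cd8a and Cd4 the rise was smaller, from 0.25 ± 0.22 to 1.30 ± 0.51. That between Ighd and Ighm was -4.56 ± 0.52 and -2.65 ± 0.50. Cd8b1, Cd8a and Ighd were picked for their large rises, so these differences are given as values without a test, and the added 1 pulls those of low genes such as Cd4 towards 0. Ighm itself had 876 ± 273 against 1276 ± 317 FPKM (log2 fold change 0.57, SE 0.27, adjusted p = 0.23). Of 42 tested immunoglobulin kappa variable genes 4 were higher and 0 lower, and 39 had positive log2 fold changes (median 0.83). Of 40 heavy chain variable genes 29 had positive log2 fold changes (median 0.36), 0 were higher and 1 was lower, Ighv11-2, a segment common among B-1 cells, with 15.4 ± 15.4 against 1.93 ± 1.02 FPKM (log2 fold change -2.21, SE 0.48, adjusted p = 0.031). Control 3 holds its highest value (42.8 FPKM), and the call ended without control 2, diabetic 1, diabetic 2 or diabetic 4 (highest adjusted p = 0.096). Antigen receptor segments share reads with close relatives.

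Among the genes lower in diabetic samples were the adaptor Dok2, at 156 ± 17.1 against 87.3 ± 7.27 FPKM (log2 fold change -0.83, SE 0.11, adjusted p = 0.0054), and Csf2ra, the alpha chain of the GM-CSF receptor (log2 fold change -0.81, SE 0.17, adjusted p = 0.023). So were Alox5, the 5-lipoxygenase (log2 fold change -0.47, SE 0.12, adjusted p = 0.046), Tbxas1, the thromboxane synthase (log2 fold change -0.49, SE 0.11, adjusted p = 0.034), and Ltb4r1, a leukotriene B4 receptor (log2 fold change -0.78, SE 0.14, adjusted p = 0.018). Others were Lmna (log2 fold change -0.66, SE 0.14, adjusted p = 0.025), the actin regulators Gsn (log2 fold change -0.60, SE 0.14, adjusted p = 0.034) and Rhoc (log2 fold change -0.65, SE 0.13, adjusted p = 0.025), Crip1, Cd9 and the haem-regulated repressor Bach1 (log2 fold change -0.97, SE 0.21, adjusted p = 0.030). Dok2 passed in all 9 fits that left out 1 sample, Ltb4r1 in 7 and Csf2ra in 6. Rhoc passed in 5 of them, Lmna in 4, Cd9 in 3, and Gsn, Crip1 and Bach1 in 2 each. Alox5 and Tbxas1 passed in 1 each, without diabetic 3.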
